A study of Mus musculus with 2 samples.

How the data were processed

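Chromatin accessibility was measured in single nuclei of inguinal adipose tissue, a subcutaneous fat depot, from C57BL/6 mice. Per the labels, the mice carried either a UCP1 knockout or the wild-type genotype, were acclimated to cold and were then kept at 6 °C for 1 week. The tissue was digested, enriched for the mature adipocyte fraction and used to isolate nuclei, and libraries were built with the 10x Genomics single-cell ATAC protocol, per the labels' protocols. Cell Ranger ATAC and Cell Ranger were named as tools and mm10 as the genome build, per the submitters' processing notes, and their versions are not given in the sources used here.

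The deposited matrix holds counts of transposase cut sites for 87310 peaks and 4130 barcodes pooled over both samples, with 21497221 entries that are whole numbers. Whether depth was equalised between the libraries when they were pooled is not given in the sources used here, so the totals and medians per nucleus below are those of the deposited matrix and need not be the sequenced depth. Of these entries 90.1% were even, as when both ends of a fragment fall into the same peak, so each interval below was computed on pairs of cut sites. A suffix on each barcode marks its library. The 2 samples are 1 of each genotype, and neither the labels nor the files state which suffix belongs to which genotype. The libraries are therefore called library 1 and library 2 after the suffix, every ratio is given between these unlabelled libraries, and no direction by genotype was drawn. The genotype was not inferred from Ucp1 or any other value.

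Genes were taken from an NCBI RefSeq gene table of assembly GRCm38.p6, whose coordinates on the main chromosomes are those of mm10. The table gives gene starts and ends without strand or exons. A gene's value was the number of cut sites in peaks that overlap the gene or the 2 kb on either side of it, scaled to all cut sites in peaks of the same nuclei and given as CPM. The design fixed before the data were examined had named 2 kb upstream only, which needs the strand. Likewise, peaks within 1 kb of either gene end stood in for promoter peaks. A peak in the window of several genes counted for each of them. All 307 genes of the marker and process lists were found in the table, and 38 of them had no cut sites. Of the protein-coding genes, 73.2% had a peak.

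Nuclei were clustered on peaks seen in at least 10 nuclei (85247 peaks) as a binary matrix with TF-IDF weighting and a truncated singular value decomposition of 30 components. The 1 component that followed depth (|r| above 0.75) was dropped, and a 15-nearest-neighbour cosine graph was partitioned with the Leiden method at resolution 0.8 and seed 1. The 13 clusters were named from marker lists fixed before the data were examined. Markers with at least 200 cut sites were scored. A marker counted as raised at 2 times its median over clusters, a class needed at least 3 raised markers, a lead of 25 percentage points over the next class, and no class with more markers than its own among the 10 leading genes. Clusters of low depth without a marker of their class among the leading genes stayed unnamed. This scoring rule was set after the data were seen. Of 17 marker lists, 6 named 11 clusters, 10 named none, and the list of thermogenic adipocyte markers was used only inside the adipocyte-like class. No cell filter was added to the authors' barcode selection. Simulated doublets (summed pairs of nuclei, 50 neighbours, score above 0.75, a threshold set after the scores were seen) marked 3.29% of library 1 and 1.20% of library 2. Marked barcodes stayed in, and leaving them out was an alternative.

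Depth was 41176170 cut sites in library 1 and 16814706 in library 2. With 1 library per genotype and no replicate, no test between the libraries was made. Levels carry exact Poisson intervals, ratios exact conditional binomial intervals and shares exact Clopper-Pearson intervals, all at 95% and all covering counting error only. The log2 ratio of a gene was computed after adding 1 CPM to each library. For each of 16 process lists, the median log2 ratio was set beside 10000 random lists of the same size, matched on mean accessibility in 20 bins. The random range is their middle part from percentile 2.5 to percentile 97.5, and the percentile describes these libraries only. Members of a random list were drawn independently, so the range makes no allowance for genes that vary together or share peaks, and it may be too narrow for such lists. Comparisons of Ucp1 between classes of different depth also used nuclei thinned to 5000 cut sites, which left out 1184 of the 4130 nuclei.

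The rule for named genes was fixed before the data were examined. It takes Ucp1, any member of the lists (first the 2 highest and 2 lowest of each list with at least 50 cut sites), the 10 highest and 10 lowest protein-coding genes with at least 200 cut sites (gene models without a proper name left out), and the 5 leading genes of a class. A gene that this rule names in cluster 2 is not reported here. Alternatives fixed at the same time were other clustering settings, another seed, gene-end peaks, binary peaks, scaling by gene-end cut sites, and leaving out doublet-marked or the shallowest 10% of nuclei. The motif shares named in the design need a genome sequence and are not analysed here.

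The ratio and list steps were tested on simulated data drawn from the real gene means and library totals. For the adipocyte-like comparison (14284 genes, 200 of them changed), genes simulated at a log2 ratio of 1 returned a median of 0.97 and those at -2 a median of -1.90, and 95.4% of intervals of unchanged genes covered the true ratio. Of 100 simulated lists of 15 genes raised by 0.5, 100 lay above the random range, and of 100 unchanged lists 1 lay above and 3 below it. For the stromal comparison (9419 genes), genes simulated at 1 returned 0.98 and those at -2 returned -2.01. Unchanged genes of the simulation differed by counting noise only, as the intervals assume, so their coverage was nearly fixed in advance. Real log2 ratios spread further, with a standard deviation of 0.36 beyond counting noise in thinned adipocyte-like nuclei. The simulated list results therefore do not carry over to the real lists. Simulated nuclei of 4 class profiles (200 per profile) were separated into 4 clusters, with 100% in a cluster of their own profile. These were mean profiles of classes found by the same clustering, without spread within a class, so the step could hardly fail. It tested neither the endothelial-like and T or NK-like classes nor the clusters within the adipocyte-like class. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.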

Results

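Single-nucleus ATAC-seq, which maps accessible chromatin by transposase insertion, was compared between a UCP1 knockout and a wild-type sample of mouse inguinal fat after 1 week at 6 °C. UCP1 is the mitochondrial uncoupling protein of brown and beige adipocytes, and the design asks how fat chromatin in the cold differs without it. Library 1 held 2709 nuclei with a median of 10645 cut sites (quartiles 5464 and 19416), and library 2 held 1421 nuclei with a median of 7343 (quartiles 2723 and 17577). Which library came from which genotype is not stated in the sources used here, so values are given for library 1 and library 2 and no direction by genotype is drawn. Each genotype had 1 library, so differences have no replicate check, and the intervals in brackets are 95% intervals of counting error only.

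Adipocyte-like nuclei were the most frequent class, with 1386 nuclei or 51.2% [49.3 to 53.1] of library 1 and 625 nuclei or 44% [41.4 to 46.6] of library 2. Macrophage-like nuclei made up 11% [9.88 to 12.3] of library 1 and 4.79% [3.73 to 6.03] of library 2, and T or NK-like nuclei 4.32% [3.58 to 5.15] and 1.06% [0.592 to 1.74]. Mural-like nuclei (pericytes and smooth muscle) made up 6.76% [5.84 to 7.77] and 4.79% [3.73 to 6.03]. Stromal progenitor-like nuclei made up 12% [10.8 to 13.2] and 16.1% [14.2 to 18.1], and endothelial-like nuclei 4.50% [3.75 to 5.35] and 12.2% [10.6 to 14.1]. The classes were named from the marker lists. Their leading genes included C1qc and C1qb (complement components of macrophages), Kdr and Erg (endothelium), Higd1b (pericytes) and Il2rb (T and NK cells). Not all detected markers were 2-fold above other nuclei. Those that were numbered 5 of 7 for macrophage-like, 6 of 10 for endothelial-like and 6 of 8 for mural-like nuclei. For T or NK-like nuclei they numbered 5 of 8, and for stromal progenitor-like nuclei 8 of 12. The macrophage-like, mural-like and T or NK-like shares were higher in library 1 under all 10 clustering alternatives.

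The adipocyte-like share was higher in library 1 under 7 of these alternatives and in library 2 under 3. The endothelial-like share was higher in library 1 under 3 and in library 2 under 6, and in library 2 it ranged from 0 to 12.2%. The stromal share was higher in library 1 under 1 and in library 2 under 8, and in library 2 it ranged from 0 to 16.3%. Endothelial-like nuclei had a median of only 3844 cut sites in library 1 and 1754 in library 2, and the enrichment for mature adipocytes acts on all of these shares. A further 10.3% of library 1 and 17.0% of library 2 stayed unnamed. They comprised cluster 6, with 6.46% and 12.6% of the libraries, raised adipocyte markers and a median of 2856 cut sites, and cluster 10, with 3.80% and 4.43% and Ms4a6c, Flt3, H2-Ob and Cd69 among its leading genes.

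**Figure D1:**
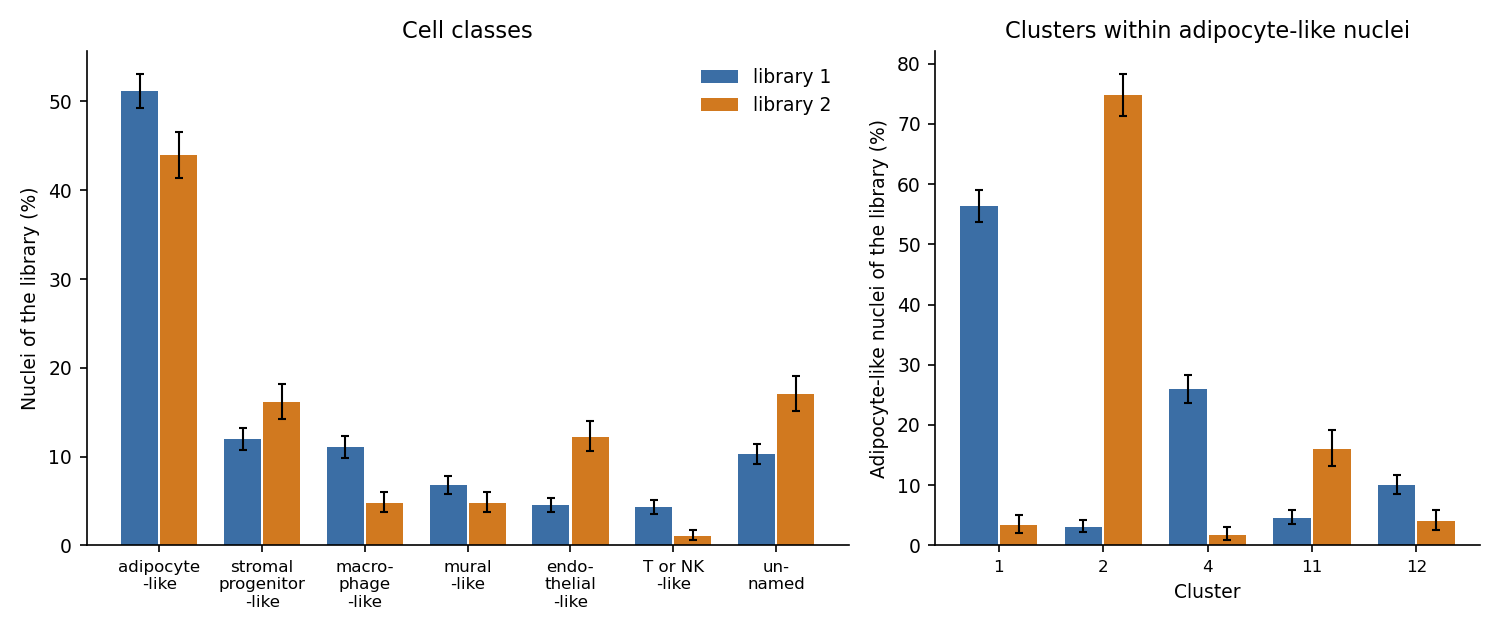
Share of each library's nuclei in each cell class (left, percent) and share of each library's adipocyte-like nuclei in each of their 5 clusters (right, percent), with library 1 in blue, library 2 in orange and 95% Clopper-Pearson intervals of counting error as bars. Cluster 2 held 3.10% of the adipocyte-like nuclei of library 1 and 74.9% of those of library 2.

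The adipocyte-like nuclei of the libraries fell into different clusters. Cluster 1 held 781 nuclei of library 1 and 21 of library 2, cluster 4 held 359 and 11, and cluster 12 held 139 and 25. Cluster 2 held 43 nuclei of library 1 and 468 of library 2, and cluster 11 held 64 and 100. Among the genes that define cluster 2 were Ucp1, Bmp8b, Otop1, Cpt1b and Fabp3, and cluster 1 was defined by Cfd (adipsin), Hp, Car3 and complement genes such as C4b. With 1 library per group, a cluster mostly of 1 library may be that library and not a cell type. Cluster 4 had the highest median depth of the adipocyte-like clusters, 37326 cut sites, and 15.4% of its barcodes were marked as doublets.

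Ucp1 (gene 22227, chromosome 8, 83290348 to 83298456, mm10) was accessible in adipocyte-like nuclei of both libraries. Its level was 11.1 CPM [9.44 to 13] in library 1 and 32.7 [28.4 to 37.5] in library 2, a ratio of 2.94 [2.38 to 3.64]. The peak over the gene start (83290007 to 83290622) was 3.83-fold [2.73 to 5.35] higher in library 2. Peaks ending 4379 bp and 11358 bp before the gene start, in no annotated gene, were 4.27-fold [3.50 to 5.24] and 3.21-fold [2.57 to 4.04] higher. A peak starting 11276 bp beyond the gene end went the other way, at 0.668 of library 1 [0.554 to 0.801]. The labels do not say which part of Ucp1 was altered, so none of these peaks checks a genotype. Without cluster 4 the Ucp1 ratio was 1.77.

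Cluster 2 held most adipocyte-like Ucp1 cut sites of both libraries, 58.4% in library 1 and 90.7% in library 2. The 43 nuclei of library 1 in this cluster had 130 CPM [105 to 160]. The 468 nuclei of library 2 had 37.4 CPM [32.4 to 43.2], so that within cluster 2 Ucp1 was 3.48-fold [2.67 to 4.48] higher in library 1. In cluster 11, with 64 and 100 nuclei, Ucp1 was at 8.51 CPM [3.92 to 17.9] in library 1 and 14.1 [7.0 to 23.7] in library 2, a ratio of library 2 over library 1 of 1.66 [0.561 to 4.21]. All adipocyte-like nuclei outside cluster 2 had 4.87 CPM [3.75 to 6.22] in library 1 and 14.8 [9.25 to 23.4] in library 2. A cut site at Ucp1 was present in 33 of 43 cluster 2 nuclei (76.7% [61.4 to 88.2]) of library 1 and in 129 of 468 (27.6% [23.6 to 31.9]) of library 2, at median depths of 33090 and 19464. Clustering again without the 1235 peaks of the process list genes, Ucp1 included, gave a cluster with 43 nuclei of library 1 and 463 of library 2, and its Ucp1 ratio was 3.44 [2.64 to 4.43]. Most clustered peaks stayed in, among them those 4379 bp and 11358 bp before Ucp1, which lie outside its window. A like cluster was therefore likely in any case, and the step does not show that the cluster is independent of accessibility at Ucp1 or thermogenic genes. With every nucleus thinned to 5000 cut sites the ratio within cluster 2 was 4.84.

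As a measure of background, Ucp1 had 8.36 CPM [4.32 to 14.6] in macrophage-like nuclei of library 1, 3.94 [1.28 to 9.18] in mural-like and 2.44 [0.826 to 4.90] in stromal progenitor-like nuclei. These intervals overlap that of its adipocyte-like nuclei outside cluster 2. In library 2 the stromal progenitor-like level was 9.17 [3.72 to 17.0], and no Ucp1 cut site was found in macrophage-like nuclei, where the interval reached 24.0. At 5000 cut sites per nucleus, 3.07% [2.19 to 4.17] of adipocyte-like nuclei of library 1 and 9.56% [7.30 to 12.2] of library 2 had a Ucp1 cut site. Of macrophage-like nuclei it was 1.49% [0.309 to 4.30] in library 1 and 0 of 22 in library 2, whose interval reaches 15.4%. Of stromal progenitor-like nuclei it was 1.08% [0.223 to 3.12] and 3.17% [0.872 to 7.93], and in both libraries the interval overlaps that of adipocyte-like nuclei. Unthinned, the shares were 6.57% and 23.2% of adipocyte-like nuclei (median depths 13662 and 18406) and 2.34% and 0% of macrophage-like nuclei (8225 and 3886).

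**Figure D2:**
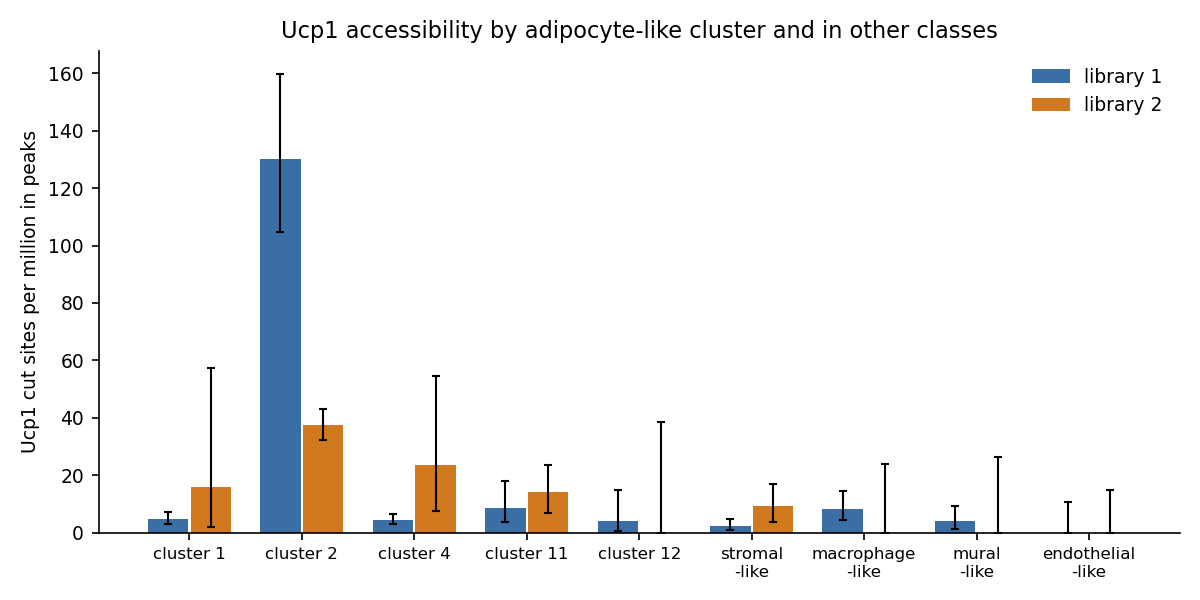
Ucp1 accessibility (CPM) in the 5 adipocyte-like clusters and in 4 other classes, library 1 in blue and library 2 in orange, with exact Poisson 95% intervals of counting error. Cluster 2 reached 130 CPM in library 1 and 37.4 in library 2, and adipocyte-like clusters 1, 4, 11 and 12 of library 1 lay between 4.11 and 8.51.

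**Figure D3:**
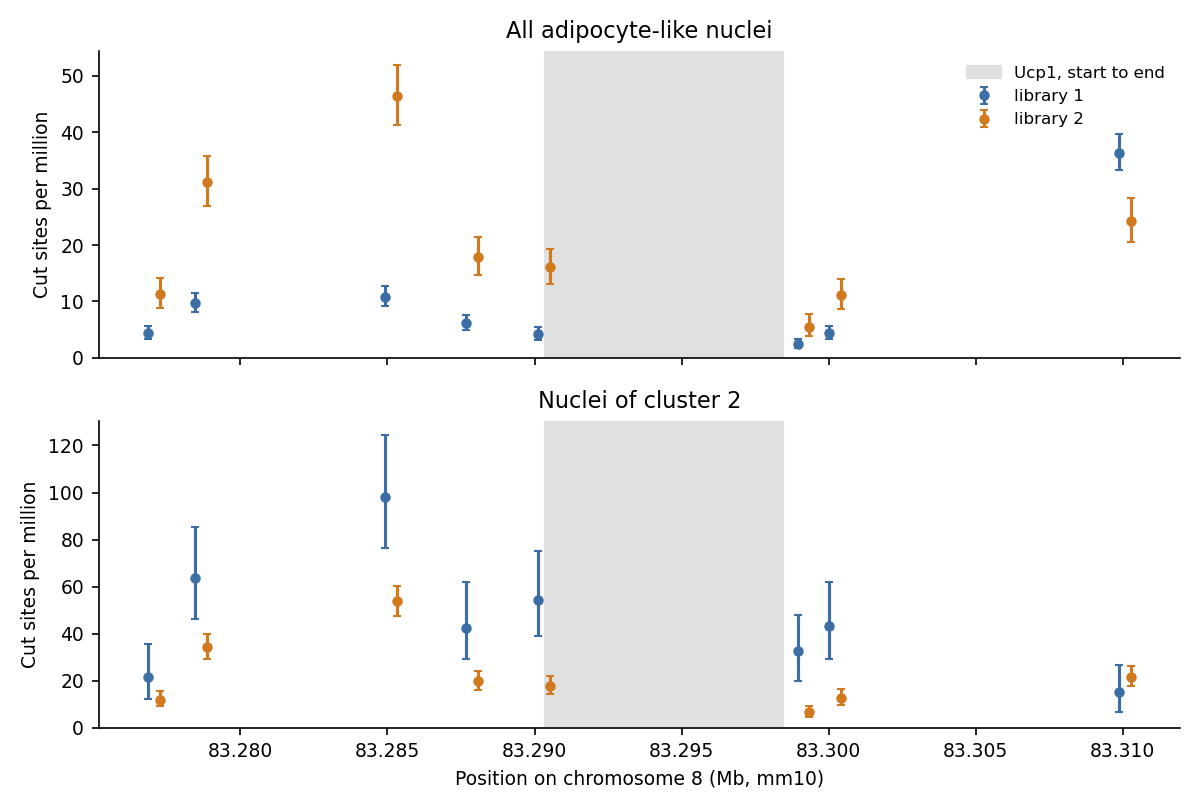
Accessibility (CPM) of each peak around Ucp1 on chromosome 8 (mm10, Mb) in all adipocyte-like nuclei (top) and in cluster 2 (bottom), library 1 in blue and library 2 in orange, offset sideways for legibility, with exact Poisson 95% intervals of counting error and the gene shaded. In the top panel 7 of 8 peaks are higher in library 2, and in the bottom panel the same 7 are higher in library 1.

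Across all adipocyte-like nuclei, genes of thermogenesis, fatty acid synthesis and glucose use were more accessible in library 2. All 15 UCP1-linked thermogenic genes were higher in library 2 (median log2 ratio 0.61, random range -0.23 to 0.17, percentile 100). Elovl3, a fatty acid elongase of brown fat that shares most of its cut sites with Pitx3, was 3.96-fold [3.54 to 4.44] higher (2.42 with each peak counted once per nucleus), the proton channel gene Otop1 3.93-fold [3.42 to 4.50] and the potassium channel gene Kcnk3 2.55-fold [2.38 to 2.75], while Ppargc1a, the thermogenic coactivator, was 1.14-fold [1.09 to 1.19] higher. Of the 13 genes of de novo lipogenesis 11 were higher (median 0.60, random range -0.31 to 0.12, percentile 100), with Scd1 at 2.63-fold [2.48 to 2.78], Elovl6 at 2.48-fold [2.31 to 2.65], Acly at 2.35-fold [2.20 to 2.52] and Fasn at 2.27-fold [2.19 to 2.34]. Fasn shares all its cut sites with the window of Ccdc57, and counting each peak once per nucleus, open or not, gave it a ratio of 1.02. In glucose use 9 of 10 were higher (median 0.48, random range -0.30 to 0.17, percentile 100), led by the glycolytic gene Pkm at 2.08-fold [1.93 to 2.23], while Pfkfb3, which drives glycolysis through fructose 2,6-bisphosphate, was at 0.546 [0.527 to 0.566].

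Fatty acid oxidation genes were higher in 10 of 12 cases (median 0.27, random range -0.27 to 0.16, percentile 99.7), with Hadha and Hadhb, which share peaks, both at 2.06-fold. Calcium cycle genes were higher in 6 of 7 measured cases (median 0.55, random range -0.34 to 0.32), with the calcium release channel genes Ryr2 at 1.85-fold [1.61 to 2.12] and Itpr2 at 1.60-fold [1.51 to 1.69]. With gene-end peaks alone the calcium cycle median was 0.094, inside its random range. Respiratory chain genes (median 0.11, 10 of 13 higher) and the creatine cycle (median -0.10, 3 of 6 higher) lay inside their random ranges. Alpl, which hydrolyses phosphocreatine in thermogenic fat mitochondria, had 154 CPM in each library, and Ckb, a creatine kinase, was at 0.767 of library 1 [0.667 to 0.881].

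Adipokine genes, inflammatory genes and immediate early genes were less accessible in library 2. In the adipokine list 6 of 10 genes were lower (median -0.43, random range -0.29 to 0.23), with Cfd, all of whose cut sites are shared with Elane and Med16, at 0.158 of library 1 [0.147 to 0.169] (0.340 with each peak counted once per nucleus), Rbp4 at 0.437 [0.340 to 0.551] and Adipoq at 0.603 [0.554 to 0.655]. In the same list, Bmp8b, a growth factor gene of thermogenic adipocytes, was 5.90-fold [4.50 to 7.93] higher in library 2 and Fgf21, an endocrine hormone gene whose window shares all its cut sites with Fut1, 2.37-fold [1.80 to 3.14]. Inflammatory genes were lower in 8 of 9 cases (median -0.49, random range -0.32 to 0.29), with Irf1 at 0.324 [0.281 to 0.372]. That median came to -0.23 without cluster 4, at percentile 3.96, and lay at percentile 3.67 after thinning, both inside the random range. All 10 immediate early genes, which respond to tissue handling, were lower in library 2 (median -0.83, random range -0.32 to 0.16), with Fos at 0.349 [0.326 to 0.374] (0.647 with each peak counted once per nucleus) and Egr1 at 0.408 [0.381 to 0.436]. Over all adipocyte-like nuclei this list differed alongside every group named here, but within cluster 2 its median was 0.25, the other way. Adipocyte-like nuclei had a median of 13662 cut sites in library 1 and 18406 in library 2.

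Genes of lipolysis and the glyceride cycle went both ways (8 of 15 higher, median 0.00). Pck1, the enzyme of glyceroneogenesis, was at 0.318 of library 1 [0.299 to 0.338], and Pnpla2, the gene of adipose triglyceride lipase, at 0.580 [0.555 to 0.606] with all its cut sites shared with neighbours, whereas the glycerol channel gene Aqp7 was 1.96-fold [1.74 to 2.20] higher. Among adipogenic regulators (median -0.04), Cebpa was at 0.530 [0.495 to 0.566], Irf4 at 0.581 [0.501 to 0.671] and Ebf2 1.61-fold [1.51 to 1.71] higher, with Pparg at 1.06 [1.02 to 1.12]. The medians of adrenergic signalling (-0.05), extracellular matrix (-0.15), stress response (-0.12) and proliferation (-0.10) also lay inside their random ranges.

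Over the genome, the protein-coding genes highest in library 2 relative to library 1 were Pgm5 (13.8-fold [7.86 to 24.4]), Dcdc2c, H1f7, Cntn6, Zscan18, Bmp8b, Spock3, Btn1a1, Acot12 and Ttbk1. The lowest were Cfd, Med16, whose window shares the Cfd peaks, Car3 (0.231 [0.216 to 0.246]), Serpina3j, C4b (0.233 [0.188 to 0.287]), Btnl6, Ffar2 (0.268 [0.217 to 0.330]), Cfb, Saa2 and Tmem176b. Car3 encodes an abundant adipocyte carbonic anhydrase, C4b and Cfb complement factors, and Ffar2 a receptor for short-chain fatty acids. Most of these genes also define cluster 1 or cluster 2. In library 1 most adipocyte-like nuclei lay in clusters 1 and 4, and in library 2 in cluster 2. The median log2 ratio over 14284 genes was -0.01.

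**Figure D4:**
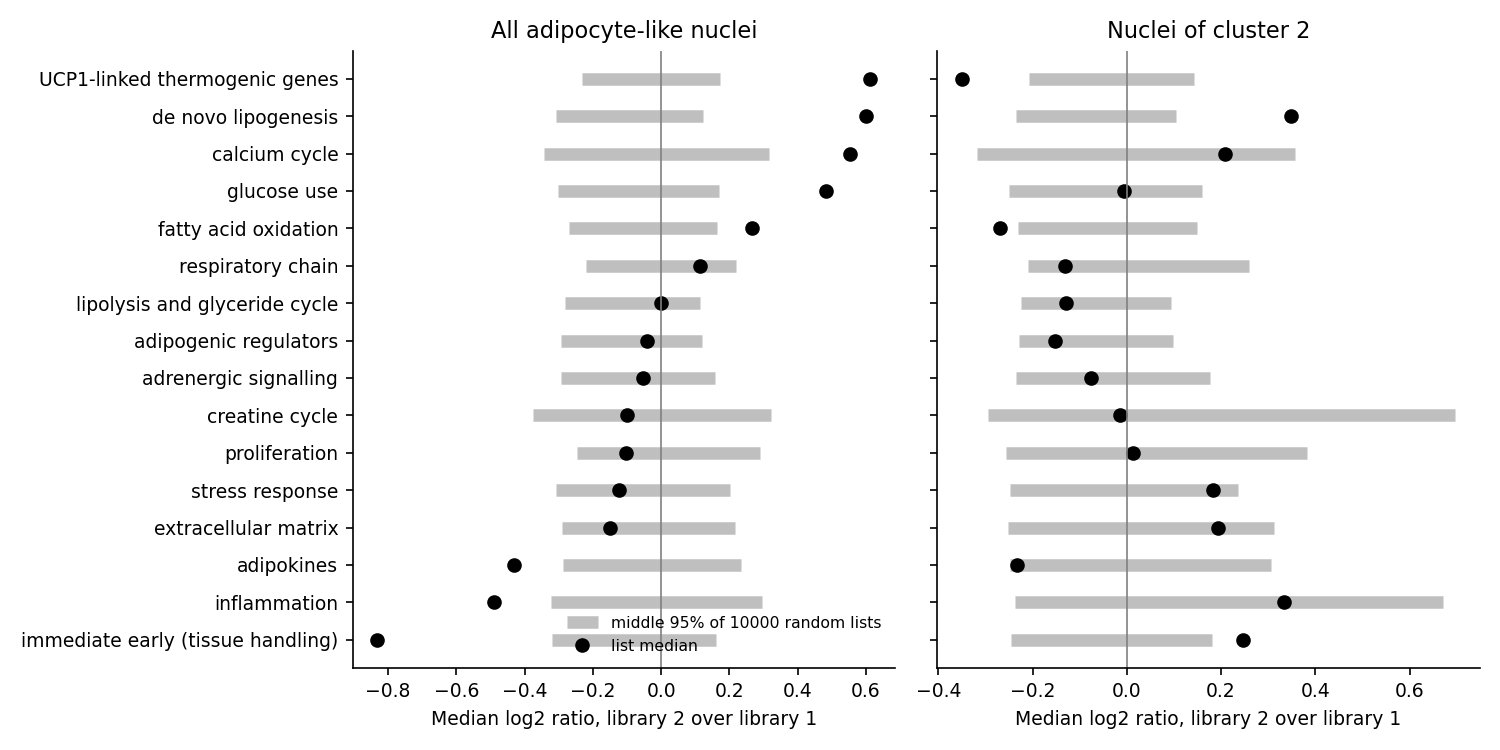
Median log2 ratio of library 2 over library 1 for each process list (black points) in all adipocyte-like nuclei (left) and in cluster 2 (right), with grey bars for the middle 95% of 10000 random lists matched on accessibility. The thermogenic median is 0.61 on the left and -0.35 on the right, while that of de novo lipogenesis is 0.60 and 0.35.

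Within cluster 2, which holds the highest Ucp1 level of both libraries, thermogenic genes were less accessible in library 2 and lipogenic genes more. Of the 15 thermogenic genes 14 were lower in library 2 (median -0.35, random range -0.21 to 0.14, percentile 0.050), among them Ppara, a lipid-sensing receptor gene, at 0.583 of library 1 [0.485 to 0.704], Cox8b at 0.702 [0.548 to 0.913] and Otop1 at 0.719 [0.584 to 0.892]. The intervals of Ppargc1a (0.972 [0.867 to 1.10]), Kcnk3, Gk, Cox7a1 and Dio2 included 1. Elovl3 was the exception at 2.02-fold [1.52 to 2.67] higher. Of the 13 lipogenic genes 12 were higher (median 0.35, random range -0.23 to 0.10), with Scd1 at 2.46-fold [2.01 to 3.03], Acly at 1.86-fold [1.53 to 2.28] and the citrate carrier gene Slc25a1 at 1.81-fold [1.39 to 2.39]. Fatty acid oxidation genes were lower in 10 of 12 cases (median -0.27, random range -0.23 to 0.15), with Acadl at 0.686 [0.546 to 0.862] and Ppargc1b at 0.691 [0.613 to 0.783]. The immediate early median was 0.25 here, above its random range of -0.24 to 0.18, and Fos was at 1.19 [0.937 to 1.53]. Unlike over all adipocyte-like nuclei, the medians of glucose use (-0.006), inflammation (0.33), adipokines (-0.23) and calcium cycle (0.21) lay inside their random ranges.

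Ucp1 had the lowest log2 ratio (-1.77) among the protein-coding genes that passed the minimum of cut sites for ranking in cluster 2. Next came Galnt16 (0.326 [0.205 to 0.506]), Nrap, Cpn2, Tnnc2, Slc27a2, Mns1, Eef1akmt3 and Grik1. The minimum counted both libraries together, and cluster 2 had 1384398 cut sites in library 1 and 10134852 in library 2. A gene much lower in library 2 could therefore miss the minimum, so this rank does not cover all genes. The highest in library 2 were Lgals3, the galectin-3 gene, at 9.29-fold [3.13 to 45.4], Htatip2, Anxa4, Cntn6, Btn1a1, Matn3, Isg20, Map1b, Slc30a4 and Nceh1, each with 12 or fewer cut sites in library 1. The peak over the Ucp1 start was 3.05-fold [2.06 to 4.56] higher in library 1, and the peaks 4379 bp and 11358 bp before the gene were 1.83-fold [1.38 to 2.40] and 1.85-fold [1.30 to 2.59] higher. Other genes of the lists that were higher in library 2 included Gdf15, a stress-induced hormone gene (2.29-fold [1.52 to 3.77]), Asns (1.92-fold [1.2 to 3.23]) and Fgf21 (3.41-fold [1.29 to 12.8], 8 cut sites in library 1). The library 1 side of this comparison rests on 43 nuclei, and thermogenic genes help to define the cluster. The lists were not compared within cluster 11.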

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

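Genes of the Y chromosome were not part of any comparison above, and they carried cut sites in both libraries, far above the limit that a count of 0 would allow. Summed over Kdm5d, Eif2s3y, Uty and Ddx3y, library 1 had 69.3 CPM [65.7 to 73.0] and library 2 had 60.8 [55.6 to 66.3]. These values argue against an all-female source for either library. The sex of the mice is not given in the labels, and whether all of them were male was not tested.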

How the results depend on the processing

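Alternatives were run for depth, class shares, the adipocyte-like list medians, Ucp1, its cluster 2 ratio, Elovl3, Fasn, Cfd and Fos, and not for other genes, other classes or the cluster 2 medians. Among those run, no ratio and no list median outside its random range changed direction, but the adipocyte-like share was higher in library 2 under 3 of 10 clustering alternatives. Chosen only after the data were seen were clustering without list peaks, adding the low-depth cluster 6, leaving out cluster 4, and thinning. The adipocyte-like share of library 1 was 54.4% at resolution 0.4, 56.1% at 1.2, 56.4% with 20 components, 42.8% without the shallowest 10% of nuclei, 55.9% without doublet-marked barcodes, 37.7% with peaks in at least 50 nuclei, 37.2% with seed 2, 56.1% without list peaks and 57.6% with cluster 6; that of library 2 was 48.1%, 47.6%, 48.1% and 56.6% at resolution 1.2, with 20 components, without list peaks and with cluster 6. The Ucp1 ratio was 1.77 without cluster 4, and its cluster 2 ratio 4.84 after thinning. With gene-end peaks the list medians were 0.79 (thermogenic), 0.094 (calcium cycle), 0.18 (fatty acid oxidation), 0.55 (glucose use) and -0.89 (adipokines). Binary peaks gave 0.53 (thermogenic), 0.31 (lipogenesis), 0.29 (glucose use), -0.27 (adipokines) and -0.37 (immediate early). Scaling by gene-end cut sites moved the median of all genes from -0.01 to 0.09 and gave 0.72, 0.66, 0.71, 0.37, 0.59, -0.33 and -0.73 for thermogenic, calcium, lipogenesis, oxidation, glucose, adipokine and immediate early genes. Without cluster 4 the medians were 0.50 (thermogenic), 0.42 (lipogenesis), 0.31 (glucose use), -0.55 (adipokines), -0.23 (inflammation) and -0.95 (immediate early), and after thinning the immediate early median was -0.96. Beyond the shift under gene-end scaling, the cause was not tested. Among other values, 80 class shares, 70 list medians and 24 gene or depth values stayed inside their counting intervals, and 20, 10 and 12 moved outside them. The thermogenic median ranged from 0.50 to 0.79 over its 10 alternatives. The motif comparison with 2000 peaks per class was not run. No paired analysis was possible because each genotype has 1 library. Depth limits endothelial-like and T or NK-like nuclei and, in library 2, mural-like and macrophage-like nuclei.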

Other observations

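The bounds of each test below were written before its outcome was computed but after the pattern had been seen, and the tests on nuclei thinned to 5000 cut sites were chosen after the data were seen. In stromal progenitor-like nuclei, 13 of 15 thermogenic genes were higher in library 2 (median log2 ratio 0.47, random range -0.23 to 0.27), with Kcnk3 at 3.44-fold [1.90 to 5.84], Cpt1b, whose window is shared with Chkb, at 3.51-fold [1.32 to 9.59] and Elovl3 at 1.07 [0.625 to 1.78]. Immediate early genes were higher there too, in 8 of 10 cases (median 0.18, random range -0.18 to 0.14), with Fos at 1.61-fold [1.44 to 1.80], the opposite of adipocyte-like nuclei. De novo lipogenesis (median 0.21, random range -0.18 to 0.17, 9 of 13 higher) and the stress response (median 0.26, random range -0.24 to 0.22, 7 of 9 higher) also lay above their random ranges, with Thrsp, a lipogenic regulator, at 2.09-fold [1.32 to 3.19] and Atf3, a stress-induced transcription factor gene, at 1.39-fold [1.17 to 1.66]. Stromal clusters 3 and 9 held both libraries, with median depths of 16838 in library 1 and 6831 in library 2.

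In mural-like nuclei the immediate early median was -0.59 (random range -0.30 to 0.28), with Fosb at 0.327 [0.195 to 0.516] and Jun at 1.03 [0.763 to 1.37]. In macrophage-like nuclei, 8 of 12 fatty acid oxidation genes were lower in library 2 (median -0.53, random range -0.40 to 0.39), on few cut sites (Hadha 170 and 8). Among the 10 lowest ratios of the same nuclei, Pck1 was at 0.0766 of library 1 [0.00192 to 0.435], Cfd at 0.180 [0.0485 to 0.467], Slc2a4 at 0.197 [0.0402 to 0.589], Plin5 at 0.201 [0.0648 to 0.477] and Fabp4 at 0.208 [0.0560 to 0.541], whereas Adipoq was at 0.849 [0.265 to 2.10], Pparg at 1.13 [0.670 to 1.79] and Scd1 at 2.27 [1.13 to 4.18]. The adipokine median lay inside its random range (-0.86, range -1.03 to 0.33), and 4.09% of these barcodes were marked as doublets. In T or NK-like nuclei 8 of 10 immediate early genes were lower in library 2 (median -0.60, random range -0.47 to 0.51), with Nr4a1 at 0.295 [0.116 to 0.715], on 15 nuclei and 8 to 30 cut sites per gene in library 2. In endothelial-like nuclei the adrenergic list lay just above its random range (median 0.44, range -0.63 to 0.37, percentile 98.2, 6 of 11 higher). The phosphodiesterase gene Pde4d was at 2.66-fold [2.06 to 3.52] and Prkaca, a protein kinase A subunit gene, at 0.532 [0.335 to 0.815]. All 16 process lists were compared in each of the mural-like, macrophage-like, T or NK-like and endothelial-like classes. With so many comparisons some medians would fall outside their random ranges by chance alone. The list medians outside their ranges in these classes may therefore be chance results.

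The higher thermogenic median in adipocyte-like nuclei of library 2 was set against technical differences between the libraries. The greater weight of deep nuclei in the sums did not account for it. At 5000 cut sites per nucleus the median was 0.62 [0.54 to 0.83], against a random range up to 0.23. Thinning keeps the expected make-up of each nucleus, so it cannot exclude a bias that comes with depth. With library 1 restricted to the 346 nuclei lowest for immediate early genes, the immediate early median went from -0.83 to -0.14 and the thermogenic median to 0.33 [0.21 to 0.45], still above its random range of up to 0.12. The kept nuclei were also deeper, with a median of 21726 cut sites against 13662 in all adipocyte-like nuclei of library 1. A tissue handling response may carry part of the difference, but the test cannot separate it from this change in the nuclei used. A bias of the whole library cannot be told apart, since the spread of gene ratios beyond counting noise in stromal nuclei was 0.63 of that in adipocyte-like nuclei thinned to the same totals (0.22 and 0.36), and the genotype stays untested for want of a key from suffix to genotype.

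The thermogenic median in stromal nuclei could come from adipocyte chromatin carried into other barcodes. Among genes at least 4 times as accessible in adipocyte-like nuclei, 46 that were higher in library 2 adipocytes had a median stromal log2 ratio of 0.76 and 27 that were lower had 0.13, a difference of 0.63 (0.20 to 1.15 over resampled genes), where carry-over predicted more than 0.3. The 27 genes had a median of -1.21 in adipocyte-like nuclei yet were not lower in stromal nuclei. Carry-over of an equal share in both libraries would not give that, but a larger share in library 2 could, and these shares were not measured. A bias of the whole library would give a difference of the same sign, and Elovl3, 3.96-fold higher in adipocyte-like nuclei, was at 1.07 in stromal nuclei. Thermogenic medians lay inside their random ranges in macrophage-like (-0.51), mural-like (0.40), endothelial-like (0.50) and T or NK-like nuclei (0.60).

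Within cluster 2, the lower Ucp1 of library 2 might reflect milder thermogenic nuclei in its larger share. Each of the 43 library 1 nuclei was set beside the 3 library 2 nuclei nearest in their share of cut sites at 200 other genes that mark the cluster in both libraries (median share 1.88% and 1.86% after matching, 1.59% in all library 2 nuclei). Ucp1 was still 3.68-fold [2.54 to 5.28] higher in library 1, so a difference in this share did not account for it. The share differed little before matching, and nuclei were not matched on depth or on thermogenic genes alone. Milder thermogenic nuclei in library 2 therefore cannot be excluded. The other thermogenic genes were not compared in matched nuclei, so for them too the explanation stays open. The difference rests on 43 nuclei of 1 library, and the genotype stays an untested explanation because neither the altered allele nor the genotype of each library is known here.

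A further hypothesis was that the same nuclei carry the thermogenic and the lipogenic genes. At 5000 cut sites per nucleus, the rank correlation of both list sums over nuclei was 0.072 in library 1 and 0.12 in library 2, at percentiles 93 and 98 of 200 random pairs of matched lists, so only library 2 lay above the random range and the hypothesis stays undecided.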
